A study of Rattus norvegicus with 81 samples.

How the data were processed

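Total RNA from the caudal mammary glands of 81 female Sprague-Dawley rats, 250 ng per array with an RNA integrity number of at least 7, was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The animals formed 18 groups, each a combination of treatment and exposure window, and every sample carried a batch label, here written 1 or 2 (in words in the labels and figures). Batch was spread over the groups of 5 animals as 3 and 2 arrays. TCS after PND 1-20 held 3 and 1, and the groups of 3 animals held batch 1 alone.

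The deposited values were log2 expression values per transcript cluster, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. RMA is a method that corrects background, normalizes quantiles and summarises probes. Software versions, the annotation release and a genome build were not given in the sources used here, so no coordinates are printed. The deposited value table held 36685 transcript clusters for MPB, TCS and OIL arrays but 7780 for DEP arrays. The DEP columns of the value table equalled those of a separate deposited table of DEP and OIL arrays to within 1.78e-15. In that table the OIL values differed from those of the value table by -0.115 on average (SD 0.199). The clusters kept there had a mean log2 value of at least 4.88 and an SD over arrays of at least 0.15. It held 0.376% of the named clusters with a mean under 6 and 45% of the others. The SD over clusters of the difference between batch means was 0.169 in the OIL arrays of the DEP and OIL table and 0.401 for the same clusters in the OIL arrays of the value table, and 0.0231 over all arrays of the DEP and OIL table, although no label states a batch adjustment. DEP was therefore compared with OIL only within that table, and DEP was tested against neither MPB nor TCS. All 20 OIL arrays present in both tables matched their own column best (lowest r = 0.98). The chronic arrays, 3 of TCS and 3 of OIL, had been normalized by themselves, so OIL at PND 146 was not tested against OIL at PND 63.

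Each comparison was fitted on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Of the clusters, 18511 carried 1 gene symbol in the platform annotation, 575 carried several and 17599 were not listed. Of a gene's clusters the one with the highest mean was used, which gave 18166 genes, or 6762 in the DEP and OIL table, with no filter on low values. Of the clusters with 1 symbol, 18394 had an Entrez identifier that matched the reference gene table, and no symbol was replaced. The model held all groups killed at the same age, with batch as a term except in the chronic window. The age comparisons of OIL were fitted on the 20 OIL arrays of the short windows. Tests were 2-sided, p was adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. A fold is given as a log2 difference ± its standard error (SE), and a group level as a mean ± SD. Differences between window effects were tested as contrasts, and across the 4 short windows with limma's moderated F test.

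Shifts of 47 gene lists, 16 of them cell type markers, were tested with camera at a preset correlation between genes of 0.01, and again with the estimated correlation. A list needed 5 measured members: 722 of the 832 members were measured, 574 of them in the DEP and OIL table, where 45 lists could be tested. Benjamini-Hochberg adjustment ran over 603 list tests for the comparisons of a chemical with OIL, 141 for OIL alone, 139 for the differences between perinatal effects and 188 for MPB against TCS. Each list is given with the median log2 difference of its members. Numbers of members higher or lower count signs, and for part of the lists the number past an adjusted p of 0.05 over the list alone is given and named as such. A list's score in an array was the mean over members of the log2 value minus its mean over all arrays of the data set. No list past the threshold had a median and a mean of opposite sign. Of the 101 list calls in the comparisons of a chemical with OIL that were followed through the alternatives, none held with an estimated correlation, nor did any list call in the other comparisons.

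Similarity of 2 chemicals was the Pearson correlation across genes of their log2 differences from the same OIL arrays, for 12 pairs. It was set beside 100 simulations of unchanged groups sharing those controls and beside the value with the OIL arrays split between the chemicals. The simulations drew genes independently of each other. Genes are not independent replicates, so no p is given for it.

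The comparisons, the lists and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold. Where fewer than 10 passed, it took all of them and the 5 with the smallest p in each direction, as values. It added up to 4 members of each list past the threshold and 18 sentinel genes. Chosen after values were seen were the limit of 0.5 on the muscle score that set aside arrays rich in muscle transcripts, the genes and scores searched for single outlying arrays, the lists followed through the alternatives, the list medians within batches, the splits with array weights, the splits that keep the batches, the clock test of Nr1d1 and the tests of an OIL group high by itself for interferon genes and Hp.

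The fitting steps were tested on simulated data with residual spreads like those of the arrays. Over 6762 genes, for DEP against OIL after PND 21-41, 28.4% of simulated log2 changes of 0.5 were called, 79.1% of those of 1 and 95.5% of those of 2. Over 18166 genes, the shares for MPB against OIL after PND 42-62 were 55.2%, 91% and 100%. For TCS against OIL after GD 1-20 they were 62.7%, 92.5% and 98.5%, and in the chronic window 4.5%, 55.2% and 83.3%. Unchanged genes made up 9.4% of the calls for DEP against OIL after PND 21-41 and 1.8% for MPB against OIL after PND 42-62.

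The alternatives were: no batch term, each batch alone, 1 fit over all arrays of a data set, only the groups compared in the fit, the table deposited for that chemical, quantile normalization again, a mean log2 value of at least 5, all transcript clusters, eBayes with trend and robust, array weights, muscle and B cell scores as covariates, an estimated correlation for the lists, OIL arrays split between chemicals, and leaving out each array in turn. Leaving out the arrays rich in muscle transcripts was added after the data were seen. Array data have no read depth, and the number of arrays limits the precision. Array medians lay between 7.09 and 7.27 in the MPB, TCS and OIL set, 8.18 and 8.39 in the DEP and OIL table, and 5.34 and 5.43 in the chronic set, so levels are compared only within a set.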

Results

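The data were mammary gland expression profiles of 81 female Sprague-Dawley rats given diethyl phthalate (DEP), methyl paraben (MPB), triclosan (TCS) or the vehicle, olive oil (OIL), through the dam or by oral gavage at low doses. Exposure covered gestation days (GD) 1-20, postnatal days (PND) 1-20, PND 21-41, PND 42-62 or the chronic window from PND 1 to the end of lactation. Glands were taken at PND 21 after both perinatal windows, at PND 42, at PND 63 and at PND 146. Each group held 5 arrays, except TCS after PND 1-20 (4) and TCS after PND 21-41, TCS after PND 42-62 and both chronic groups (3 each). Correlations between arrays of the MPB, TCS and OIL set ranged from 0.9158 to 0.9947. Values are log2 expression, and precision was limited by the number of arrays.

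The glands differed widely in their content of muscle and lymph node transcripts, within groups as well as between them. Acta1, the actin of skeletal muscle, ranged from 7.96 to 13.69 in the 5 arrays of MPB after GD 1-20 and from 7.70 to 8.68 in OIL after GD 1-20. Scores of the B cell and lymph node list ran from -1.62 to 1.33 within DEP after GD 1-20.

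**Figure D1:**
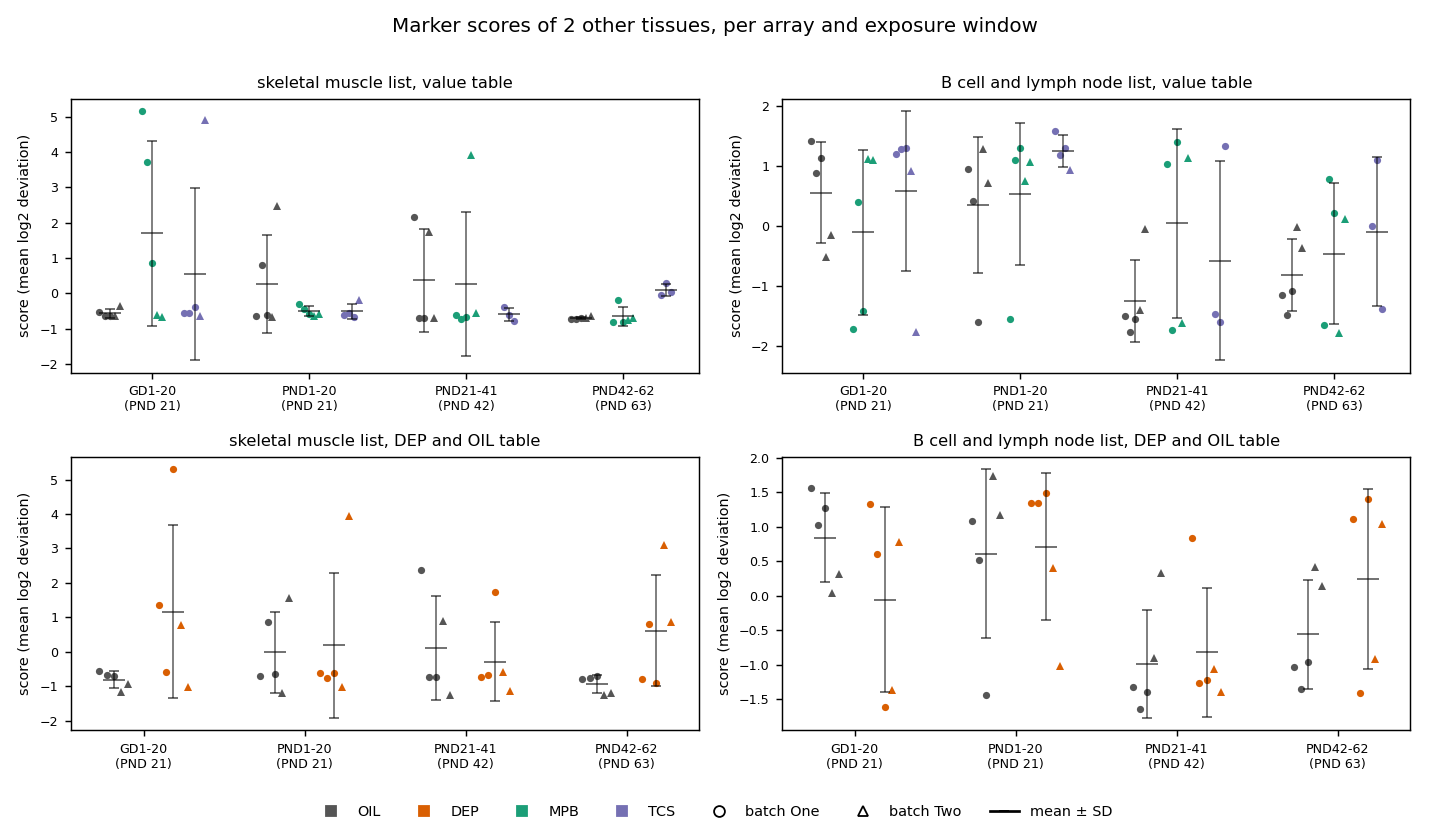
Score (log2, mean over list members minus the mean over all arrays of the set) of the skeletal muscle and the B cell and lymph node lists in each array, by window, with the MPB, TCS and OIL arrays above and the DEP and OIL table below; colour gives the group, circles batch 1, triangles batch 2, and bars the mean ± SD. Muscle scores reached 5.15 in MPB after GD 1-20 and 5.30 in DEP after GD 1-20, while B cell scores spread over a wide range within most groups.

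The OIL groups first show how the gland of vehicle animals differed with age, the background for the chemicals. Between PND 21 and PND 42 many milk protein and epithelial genes rose. Csn3, the kappa-casein gene, rose from 6.59 ± 0.61 (SD, n = 10) to 12.58 ± 0.21 (n = 5, adjusted p = 2.2e-12), and Pgr, the progesterone receptor, rose by 3.83 ± 0.47 (adjusted p = 1.7e-05). Olah, a thioesterase of milk fatty acid synthesis, rose by 3.77 ± 0.26, whereas Igf2, a fetal growth factor, fell by 2.49 ± 0.21 and Cd3g, of the T cell receptor complex, fell by 3.28 ± 0.65. In all, 2174 genes rose and 1898 fell in limma.

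All 19 luminal epithelium genes were higher at PND 42 (median log2 difference 1.48), and adjusted over the list alone all 19 passed, among them Prlr, the prolactin receptor (2.11 ± 0.20). White adipocyte genes were lower (median -0.62, 17 of 19 passed over the list alone), as were B cell and lymph node genes (median -1.56, 14 of 14 passed). The adjusted p of these lists was 4.49e-13, 3.71e-12 and 3.21e-07, and with an estimated correlation the adjusted p was 0.37, 0.306 and 0.483. Milk protein genes (median 0.82, 12 of 18 up and 2 down over the list alone) and estrogen response genes (median 0.47, 11 of 18 up) were higher, with adjusted p = 0.251 and 0.28 with an estimated correlation. The count was 1267 in batch 2 alone, 1645 with muscle and B cell scores as covariates and 2029 without arrays rich in muscle transcripts.

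Between PND 42 and PND 63 of OIL, 78 genes rose and 64 fell. Pcsk2, a prohormone convertase, rose by 2.07 ± 0.21 (adjusted p = 0.00011), Wap, whey acidic protein of milk, rose by 2.65 ± 0.60 (adjusted p = 0.043), and Eln, elastin, fell by 0.77 ± 0.12 (adjusted p = 0.0081). Interferon response genes were higher in 19 of 19 members (median 0.76), 17 of which passed adjusted over the list alone, including the regulator Irf7 (0.95 ± 0.18). Fibroblast and extracellular matrix genes were lower (median -0.32, 13 of 20 passed), and milk protein genes were higher (median 0.59, 8 of 18 passed). These 3 lists had adjusted p of 2.91e-21, 2.93e-10 and 1.96e-09, and adjusted p of 0.222, 0.381 and 0.0961 with an estimated correlation. T and NK cell genes (median 0.58, 16 of 16 positive) and macrophage genes (median 0.16, 14 of 14 positive) were higher beside them, and erythroid (median -0.61), white adipocyte (median -0.22) and skeletal muscle genes (median -1.10, and -0.05 without the arrays rich in muscle transcripts) lower. For these 5 lists the adjusted p was 3.24e-05, 0.00155, 0.000134, 0.00447 and 2.78e-05, and with an estimated correlation adjusted p = 0.503, 0.496, 0.28, 0.73 and 0.591. The count of 142 fell to 3 in batch 1, 0 in batch 2 (1807 at an unadjusted p under 0.05 in limma) and 12 with no batch term. Leaving out OIL after PND 21-41 replicates 1 to 5 in turn gave 411, 40, 9, 20 and 12, and leaving out OIL after PND 42-62 replicates 2 to 5 gave 11, 8, 70 and 15.

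The OIL groups after GD 1-20 and PND 1-20 had received no chemical and were killed at the same age. Hp (transcript cluster 17733422), haptoglobin, an acute phase protein that binds hemoglobin, was the 1 gene past the threshold, 8.05 ± 0.29 (SD, n = 5) after GD 1-20 and 7.49 ± 0.20 (n = 5) after PND 1-20, a log2 difference of 0.56 ± 0.09 (adjusted p = 0.0339). Cell cycle genes were lower after GD 1-20 (median -0.67, 23 of 24 negative, 0 passed over the list alone) and endothelial genes higher (median 0.25, 11 of 11 positive, 5 passed), with a cell cycle median of -0.44 without OIL after PND 1-20 replicate 3. Their adjusted p was 3.71e-12 and 8.03e-09, and with an estimated correlation the adjusted p was 0.471 and 0.28. Luminal epithelium genes (median -0.58, 18 of 19 negative) and skeletal muscle genes (median -0.82, 16 of 16 negative) were lower too, with 0 past the threshold over either list alone, adjusted p of 2.95e-05 and 0.0292, and adjusted p of 0.574 and 0.841 with an estimated correlation. The luminal median was -0.29 without OIL after GD 1-20 replicate 2 and -0.34 without OIL after PND 1-20 replicate 3. The Hp call remained when OIL after GD 1-20 replicate 4 or OIL after PND 1-20 replicate 1 or 5 was left out, and was lost without any 1 of the other 7 arrays (adjusted p = 0.0766 to 0.243).

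DEP after GD 1-20 went with higher cell cycle genes and lower endothelial genes at PND 21. Of 24 cell cycle genes 23 were above OIL (median 0.54, 0.42 in batch 1 and 0.70 in batch 2), with the mitotic kinase Cdk1 at 0.67 ± 0.30 and its cyclin Ccnb1 at 0.64 ± 0.29. All 10 endothelial genes were below OIL (median -0.31, -0.21 and -0.36 in the batches), and 2 passed adjusted over the list alone, Egfl7, a secreted vessel protein (-0.46 ± 0.14), and Vwf, von Willebrand factor (-0.42 ± 0.13). The adjusted p of these lists was 5.19e-09 and 2.3e-05, and adjusted p = 0.774 for each with an estimated correlation. Skeletal muscle genes were higher (median 2.02, 2.79 and 0.80 in the batches) and B cell and lymph node genes lower (median -0.87, -1.16 and -0.42) in the same arrays, with adjusted p = 0.774 and 0.822 with an estimated correlation. Without the arrays rich in muscle transcripts the medians were 0.31 for cell cycle, -0.04 for endothelium (no longer past the threshold), 0.02 for skeletal muscle and -0.16 for B cell genes. OIL after GD 1-20 itself had lower cell cycle and luminal genes and higher endothelial genes than OIL after PND 1-20, as given above. The endothelium score averaged 0.089 in DEP after GD 1-20, 0.11 in OIL after PND 1-20 and 0.387 in OIL after GD 1-20. An OIL group that differed by itself was therefore not told apart from an effect of DEP.

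Luminal epithelium genes were higher in that comparison as well (median 0.47, 18 of 19 positive, 0 passed over the list alone, adjusted p = 0.822 with an estimated correlation), with a median of 0.18 without OIL after GD 1-20 replicate 2 and -0.004 without the arrays rich in muscle transcripts. Of 6 steroid synthesis and receptor genes, all above OIL (median 0.34, adjusted p = 0.774 with an estimated correlation), 1 passed over the list alone, Hsd11b2 (0.57 ± 0.14), which inactivates glucocorticoids. Pgr stood at 1.28 ± 0.50 and Esr1, the estrogen receptor alpha gene, at 0.71 ± 0.29. Cyp2e1, a cytochrome P450 of xenobiotic metabolism, was at -1.74 ± 0.48. By single genes 0 of 6762 passed in limma and 471 had an unadjusted p under 0.05, against 338 by chance, the smallest for Pkhd1l1 (-0.69 ± 0.13, adjusted p = 0.25, 7.94 ± 0.21 against 8.63 ± 0.23, SD, n = 5 each).

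DEP after PND 1-20 went the other way for cell cycle genes. All 24 were below OIL (median -0.46, -0.44 in batch 1 and -0.54 in batch 2, 0 passed over the list alone), with cyclin Ccnb2 at -0.64 ± 0.28. The median was -0.23 without DEP after PND 1-20 replicate 5, an array rich in muscle transcripts (score 3.93), and -0.27 without OIL after PND 1-20 replicate 3. Milk protein genes were lower in 15 of 17 members (median -0.26, -0.39 and -0.19 in the batches), with Cel, the bile salt lipase of milk, at -0.37 ± 0.13 and Csn3 at -0.53 ± 0.24. Their adjusted p was 2.94e-11 and 0.00903, and adjusted p = 0.774 for each with an estimated correlation. Luminal epithelium genes had a median of -0.59 (adjusted p = 0.797 with an estimated correlation) but -1.05 in batch 1 and 0.13 in batch 2, so this did not hold within batches. In limma 0 genes passed and 184 had an unadjusted p under 0.05, fewer than the 338 expected by chance.

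After DEP over PND 21-41 the gland held less Nr1d1 (transcript cluster 17660843), the gene of the circadian repressor REV-ERB alpha, than after OIL. The level was 8.53 ± 0.32 (SD, n = 5) in DEP and 9.98 ± 0.18 (n = 5) in OIL, and the highest DEP array (8.87) lay below the lowest OIL array (9.70). Nr1d1 fell by 1.44 ± 0.16 (adjusted p = 0.0283), with -1.61 in batch 1 and -1.19 in batch 2, and was the 1 gene of 6762 past the threshold. In limma 153 genes had an unadjusted p under 0.05. Over the other settings without leaving out an array the adjusted p ran from 0.000206 to 0.786. The call remained without OIL after PND 21-41 replicate 4 or DEP after PND 21-41 replicate 3 or 5 and was lost without any 1 of the other 7 arrays (adjusted p = 0.0631 to 0.185).

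Among gene groups in these glands, all 10 endothelial genes were lower in DEP (median -0.17, -0.12 in batch 1 and -0.25 in batch 2, 0 passed over the list alone). Genes of lipid synthesis were higher in 13 of 17 members (median 0.20, 0.20 and 0.22 in the batches), with the regulator Srebf1 at 0.46 ± 0.17 and ATP citrate lyase, Acly, at 0.48 ± 0.20. Their adjusted p was 1.73e-05 and 0.000429, and adjusted p = 0.774 for each with an estimated correlation. Without the arrays rich in muscle transcripts neither list passed (medians -0.08 and 0.07). Cell cycle genes had a median of 0.41 (adjusted p = 0.86 with an estimated correlation), with 0.03 in batch 1 and 0.94 in batch 2. T and NK cell genes had a median of 0.24 (adjusted p = 0.86 with an estimated correlation), with 0.79 and -0.44 in the batches. Id1, a target of bone morphogenetic proteins, was at -0.70 ± 0.12 and Lep, leptin, at 0.88 ± 0.20, and neither passed.

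DEP after PND 42-62 went with lower interferon response and adipocyte genes at PND 63. All 17 interferon response genes were below OIL (median -0.62, -0.54 in batch 1 and -0.69 in batch 2), and 13 fell adjusted over the list alone, among them Irf7 (-0.98 ± 0.16) and the antiviral enzyme Oas2 (-0.77 ± 0.17). All 18 white adipocyte genes were lower (median -0.37, -0.34 and -0.38 in the batches), and 11 fell over the list alone, including Dgat2, which makes triglycerides (-0.62 ± 0.12). Of 19 luminal epithelium genes 18 were lower (median -0.35, -0.24 and -0.51, and -0.23 without DEP after PND 42-62 replicate 4) and 3 passed, with Foxa1, a partner of the estrogen receptor, at -0.47 ± 0.12. The adjusted p of these lists was 3.84e-09, 6.36e-08 and 1.44e-05, and with an estimated correlation the adjusted p was 0.774, 0.774 and 0.777.

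The same DEP arrays were richer in skeletal muscle genes (median 1.58, 0.43 in batch 1 and 3.33 in batch 2, and -0.12 without the arrays rich in muscle transcripts, adjusted p = 0.774 with an estimated correlation). B cell and lymph node genes had a median of 0.88 (1.48 and -0.13 in the batches, adjusted p = 0.807 with an estimated correlation). Nr1d1 was at -1.26 ± 0.17 and Rtp4, an interferon-inducible chaperone of taste and opioid receptors, at -0.99 ± 0.14, both with an adjusted p of 0.0805. In limma 0 genes passed and 995 had an unadjusted p under 0.05, 267 higher and 728 lower. Without the 3 DEP arrays rich in muscle transcripts, which left 2, 703 genes passed, 587 higher and 116 lower, and 1 passed without OIL after PND 42-62 replicate 4 or DEP after PND 42-62 replicate 4.

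MPB after GD 1-20 went with lower Hp at PND 21, 7.49 ± 0.18 (SD, n = 5, highest 7.75) against 8.05 ± 0.29 in OIL (n = 5, lowest 7.72). It fell by 0.56 ± 0.09 (adjusted p = 0.041), with -0.64 in batch 1 and -0.43 in batch 2, and was the 1 gene of 18166 to pass, while 731 had an unadjusted p under 0.05 in limma. Skeletal muscle genes were higher in 16 of 16 members (median 2.34), 15 of them past the threshold over the list alone, with Ckm, muscle creatine kinase, at 2.74 ± 1.13. For these lists the adjusted p was 8.65e-15 and adjusted p = 0.774 with an estimated correlation. This list had a median of 3.82 in batch 1 and -0.11 in batch 2, so the difference did not hold within batches.

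Basal and myoepithelial genes were lower in 9 of 10 members in MPB after GD 1-20 (median -0.30, -0.24 and -0.41 in the batches, 0 passed over the list alone, adjusted p = 0.774 with an estimated correlation), and the list did not pass without OIL after GD 1-20 replicate 4 (median -0.19). Complement and acute phase genes were lower in 10 of 12 members (median -0.18, -0.17 and -0.25 in the batches), of which Hp alone passed over the list alone (adjusted p = 0.774 with an estimated correlation), and the list did not pass without MPB after GD 1-20 replicate 1 (median -0.07). B cell and lymph node genes had a median of -0.63 (adjusted p = 0.834 with an estimated correlation), with -2.11 in batch 1 and 1.52 in batch 2. The Hp call was lost when any 1 of the 10 arrays was left out (adjusted p = 0.0566 to 0.291), and its adjusted p over the other settings ran from 0.00182 to 1.

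MPB after PND 1-20 gave small differences. Milk protein genes were lower in 15 of 18 members (median -0.12, -0.19 in batch 1 and -0.09 in batch 2) and endothelial genes higher in 9 of 11 (median 0.10, 0.10 and 0.09), with 0 members of either past the threshold over the list alone. Adjusted p was 0.0068 and 0.0046, and adjusted p = 0.774 and 0.778 with an estimated correlation. Milk protein genes did not pass without OIL after PND 1-20 replicate 3 (median -0.03), nor endothelial genes without MPB replicate 1 or 4 (medians 0.04 and 0.05). Skeletal muscle genes had a median of -0.82 (-0.30 and -1.65 in the batches, adjusted p = 0.824 with an estimated correlation), and -0.23 without OIL after PND 1-20 replicate 5. In limma 0 of 18166 genes passed and 302 had an unadjusted p under 0.05, against 908 by chance.

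MPB after PND 21-41 went with higher cell cycle genes and lower epithelial and fatty acid oxidation genes at PND 42. All 24 cell cycle genes were above OIL (median 0.98, 0.84 in batch 1 and 1.12 in batch 2), with the mitotic kinase Plk1 at 1.12 ± 0.47 and topoisomerase Top2a at 1.12 ± 0.50, though 0 passed over the list alone. That median was 0.64 without MPB after PND 21-41 replicate 2 and 0.29 without the arrays rich in muscle transcripts. All 19 luminal epithelium genes were lower (median -0.42, -0.30 and -0.55, 0 passed over the list alone). Of 18 fatty acid oxidation genes 17 were lower (median -0.23, -0.29 and -0.16) and 8 fell over the list alone, including Decr1 (-0.47 ± 0.11) and Acadl (-0.43 ± 0.12), enzymes of mitochondrial beta oxidation. The adjusted p of these 3 lists was 1.85e-10, 6.36e-08 and 8.2e-06, and adjusted p = 0.774 for each with an estimated correlation. White adipocyte markers were lower in the same glands in 18 of 19 members (median -0.37, -0.45 and -0.14 in the batches, 0 passed over the list alone, adjusted p = 4.49e-05, and 0.789 with an estimated correlation), as were PPAR gamma targets (median -0.33, 4 of 16 passed, adjusted p = 2.89e-05, and 0.774 with an estimated correlation).

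Terminal end bud and branching genes were also lower in MPB after PND 21-41 (median -0.31, -0.27 and -0.34 in the batches), and 6 of 18 fell over the list alone, among them Egfr, the receptor of ductal growth signals (-0.54 ± 0.17), and Gata3, a luminal transcription factor (-0.36 ± 0.12). The adjusted p was 0.0002 and adjusted p = 0.774 with an estimated correlation. B cell and lymph node genes (median 1.35, 1.80 and 0.58) and T and NK cell genes (median 1.41, 1.74 and 0.94) were higher in these arrays, each with adjusted p = 0.778 with an estimated correlation. Nr1d1 was 9.02 ± 0.22 in MPB and 10.09 ± 0.27 in OIL (-1.07 ± 0.14, adjusted p = 0.135, with -1.37 in batch 1 and -0.63 in batch 2). In limma 0 genes passed and 1788 had an unadjusted p under 0.05, 540 higher and 1248 lower, and 8 passed without OIL after PND 21-41 replicate 2 and 1 without MPB replicate 4 or OIL replicate 4.

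MPB after PND 42-62 went with lower Rtp4 (transcript cluster 17670074) and lower interferon response genes. Rtp4 was 7.35 ± 0.20 (SD, n = 5) in MPB and 8.63 ± 0.36 (n = 5) in OIL, with the highest MPB array (7.65) below the lowest OIL array (8.05). It fell by 1.28 ± 0.12 (adjusted p = 0.00317), with -1.39 in batch 1 and -1.13 in batch 2. All 19 interferon response genes were lower (median -0.76, -0.75 and -0.77 in the batches), and 18 fell adjusted over the list alone, with Irf7 at -1.13 ± 0.18 and Oas2 at -0.89 ± 0.17. The list's adjusted p was 8.31e-16 and adjusted p = 0.774 with an estimated correlation.

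Heat shock genes were higher in 11 of 11 members after MPB at PND 63 (median 0.21, 0.29 and 0.20 in the batches), and 3 rose over the list alone, among them the chaperone Hsph1 (0.82 ± 0.14). Of 19 endoplasmic reticulum stress genes (median 0.14, 0.14 and 0.29 in the batches, 0.09 without MPB after PND 42-62 replicate 1) 8 rose and 1 fell over the list alone, with Sdf2l1 at 0.81 ± 0.18. Cholesterol synthesis genes (median 0.36, 0.43 and 0.19) rose in 6 of 15 members, including Hsd17b7 (0.74 ± 0.16), and fatty acid oxidation genes (median -0.16, -0.17 and -0.15) fell in 6 of 18, including Acadl (-0.48 ± 0.10). These lists had adjusted p of 0.000116, 0.000429, 0.000681 and 0.000795, and adjusted p = 0.774 for each with an estimated correlation. Cell type markers shifted beside them: white adipocyte genes had a median of -0.22 (-0.33 and -0.07 in the batches, -0.11 without MPB after PND 42-62 replicate 3, 2 of 19 passed over the list alone) and endothelial genes -0.24 (-0.23 and -0.14, 1 of 11 passed), each with an adjusted p of 0.00219, and 0.827 and 0.774 with an estimated correlation. Rtp4 was the 1 gene of 18166 past the threshold, and 3240 had an unadjusted p under 0.05. Without MPB replicate 2 the count was 859, without MPB replicate 4 it was 2 and without OIL after PND 42-62 replicate 4 it was 8, and with array weights it was 2673.

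TCS after GD 1-20 went with lower Hp as well, 7.45 ± 0.31 (SD, n = 5) against 8.05 ± 0.29 (n = 5). Hp fell by 0.60 ± 0.09 (adjusted p = 0.0122), with -0.58 in batch 1 and -0.63 in batch 2, and was the 1 gene to pass of 18166, with 1236 at an unadjusted p under 0.05 in limma. All 11 endothelial genes were lower (median -0.27, -0.25 and -0.42 in the batches), and 5 fell over the list alone, with the receptor kinase Tie1 at -0.39 ± 0.09 and Egfl7 at -0.35 ± 0.10. White adipocyte genes were lower in 18 of 19 members (median -0.25, -0.10 and -0.43), with Cfd, adipsin, at -0.67 ± 0.20. Adjusted p values of these lists were 7.46e-08 and 0.00013, and adjusted p = 0.774 and 0.789 with an estimated correlation. OIL after GD 1-20 itself had higher endothelial and lower cell cycle genes than OIL after PND 1-20, as given above. The endothelium score averaged 0.088 in TCS after GD 1-20, 0.098 in OIL after PND 1-20 and 0.368 in OIL after GD 1-20. For these genes an OIL group that differed by itself was not told apart from an effect of TCS.

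Cell cycle genes were higher in 23 of 24 members after this treatment (median 0.36, 0.52 and 0.15 in the batches, 0.24 without TCS after GD 1-20 replicate 1 and 0.58 without replicate 5, adjusted p = 0.834 with an estimated correlation). Skeletal muscle genes had a median of 1.09 (adjusted p = 0.824 with an estimated correlation), with 0.12 in batch 1 and 2.81 in batch 2, and -0.01 without TCS after GD 1-20 replicate 5. The Hp call was lost without TCS after GD 1-20 replicate 4 or 5 or OIL after GD 1-20 replicate 1 or 2 (adjusted p = 0.0784 to 0.0921). Over the other settings its adjusted p ran from 0.00187 to 1, and it was lost within each batch and with no batch term.

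TCS after PND 1-20 (n = 4) went with lower matrix and epithelial genes at PND 21, and batch 2 held too few TCS arrays for a value of its own. Of 20 fibroblast and extracellular matrix genes 19 were lower (median -0.29, -0.45 in batch 1), and 4 fell over the list alone, among them Loxl1, which cross-links elastin (-0.52 ± 0.15), and Fn1, fibronectin (-0.43 ± 0.13). All 19 luminal epithelium genes were lower (median -0.77, -1.28 in batch 1, 0 passed over the list alone), with the transcription factor Elf3 at -0.74 ± 0.24. For these lists the adjusted p was 8.58e-10 and 5.28e-08, and adjusted p = 0.774 for each with an estimated correlation. B cell and lymph node genes were higher in the same arrays (median 0.90, 1.42 in batch 1, adjusted p = 0.797 with an estimated correlation), with a median of 0.41 without OIL after PND 1-20 replicate 3.

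Estrogen response genes were lower in 14 of 18 members (median -0.18, -0.27 in batch 1, adjusted p = 0.774 with an estimated correlation), and Pgr (-0.97 ± 0.27) passed over the list alone. Milk protein genes were lower in 14 of 18 (median -0.34, -0.47 in batch 1, adjusted p = 0.774 with an estimated correlation), and Cel (-0.54 ± 0.14) passed over the list alone. Scd, a fatty acid desaturase, was at -1.93 ± 0.59, and Stra6, the retinol transporter, at -1.11 ± 0.23. By single genes 0 passed in limma and 1133 had an unadjusted p under 0.05, 305 higher and 828 lower, with 1 past the threshold without OIL after PND 1-20 replicate 4 and 138 with array weights.

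TCS after PND 21-41 (n = 3, all of batch 1) gave lower luminal epithelium genes in 18 of 19 members (median -0.23, -0.16 with the OIL arrays of batch 1 alone) and higher T and NK cell genes in 15 of 16 (median 0.77, 0.92 in batch 1). No member of either passed over the list alone. Adjusted p was 0.00118 and 0.00134, and adjusted p = 0.822 and 0.817 with an estimated correlation, and without TCS replicate 3 the medians were -0.06 and -0.10. Nr1d1 was 9.0 ± 0.18 (SD, n = 3), at -1.12 ± 0.18 from OIL (adjusted p = 0.653), and Dbp, a clock output factor, at -0.55 ± 0.12. In limma 0 of 18166 genes passed and 364 had an unadjusted p under 0.05, and in batch 1 alone 1 passed.

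TCS after PND 42-62 (n = 3, all of batch 1) went with lower interferon response and adipocyte genes and more muscle transcripts. All 19 interferon response genes were lower (median -0.49, -0.50 in batch 1), and 5 fell over the list alone, with Oas2 at -0.82 ± 0.21. All 19 white adipocyte genes were lower (median -0.32, -0.39 in batch 1, -0.15 without TCS after PND 42-62 replicate 2), and 1 fell over the list alone, Agpat2, of triglyceride synthesis (-0.60 ± 0.15). All 16 skeletal muscle genes were higher (median 0.67, 0.73 in batch 1), 13 of them over the list alone, with Ttn, titin, at 1.40 ± 0.28. For these gene groups adjusted p was 1.27e-13, 6.31e-10 and 8.16e-25, and adjusted p = 0.774, 0.774 and 0.599 with an estimated correlation. Rtp4 was 7.82 ± 0.28 (n = 3), at -0.98 ± 0.15 from OIL (adjusted p = 0.488). Gene by gene, 0 passed in limma and 547 had an unadjusted p under 0.05, and 1 passed in a fit over all arrays of the set.

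**Figure D2:**
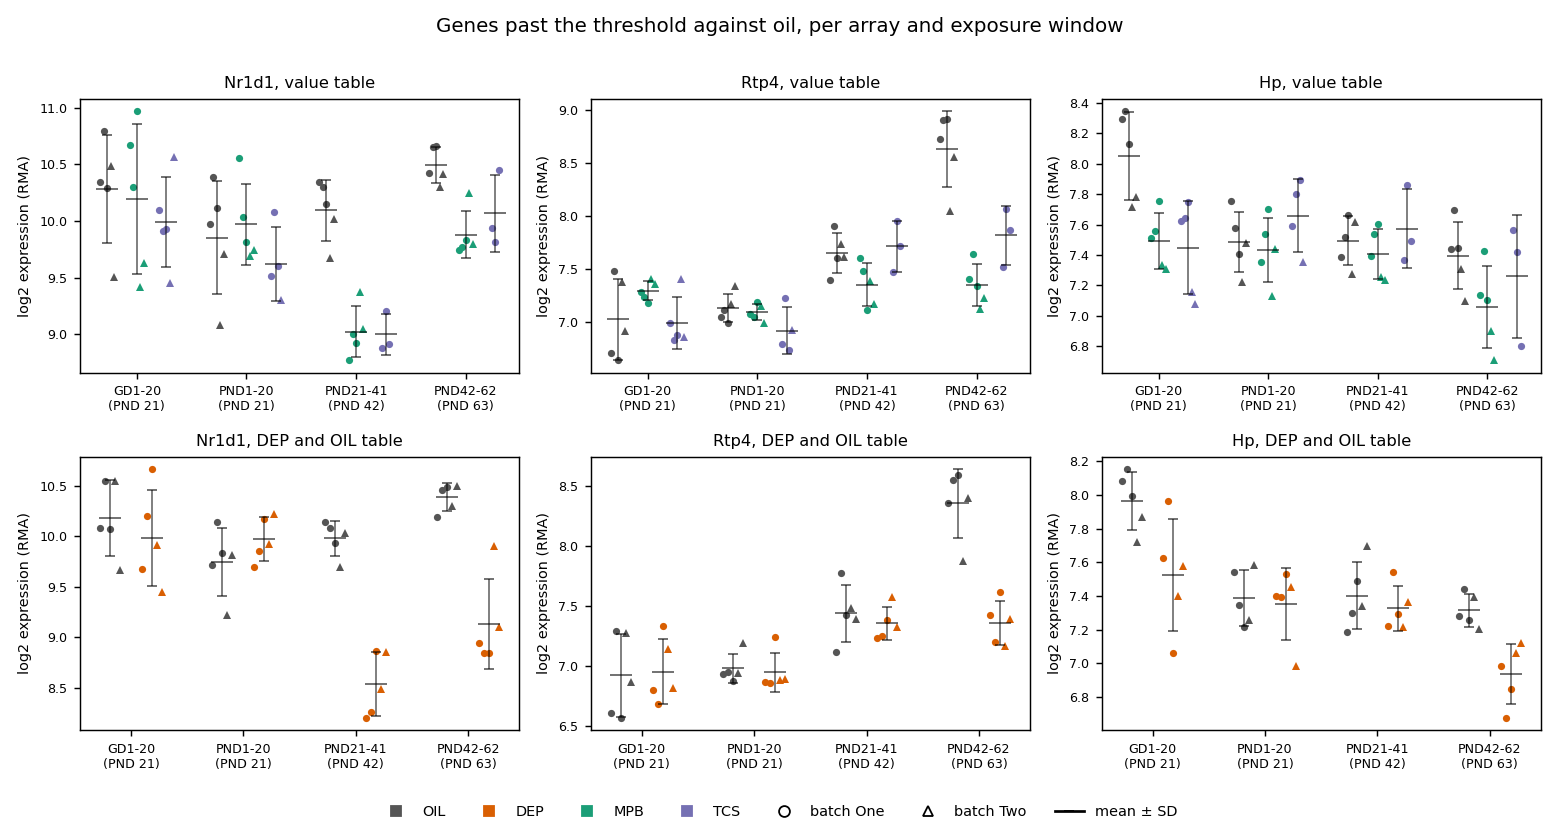
Log2 expression of Nr1d1, Rtp4 and Hp in each array by exposure window, with the MPB, TCS and OIL arrays above and the DEP and OIL table below; colour gives the group, circles batch 1, triangles batch 2, and bars the mean ± SD. Nr1d1 after PND 21-41 averaged 8.53 in DEP, 9.02 in MPB and 9.0 in TCS, and Rtp4 in OIL was 8.63 after PND 42-62 against 7.65 after PND 21-41.

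Chronic TCS (n = 3 against 3, all of batch 1, killed at the end of lactation) went with lower cholesterol synthesis genes and higher matrix and adipocyte genes. Of 15 cholesterol synthesis genes 13 were lower (median -0.65), and 8 fell over the list alone, including the squalene epoxidase Sqle (-1.14 ± 0.21). Of 20 fibroblast and extracellular matrix genes 19 were higher (median 0.63), and 1 rose over the list alone, Eln (0.90 ± 0.17). White adipocyte genes (median 0.73) rose in 11 members and fell in 1 over the list alone, with Pparg, the regulator of fat cell formation, at 0.87 ± 0.19. Without TCS replicate 3 the matrix and adipocyte medians were 0.34 and 0.42. Adjusted p values of these lists were 1.99e-08, 2.51e-07 and 1.35e-05, and adjusted p = 0.774, 0.774 and 0.778 with an estimated correlation.

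Endothelial genes were higher in the chronic TCS glands (median 0.46), 6 of 11 over the list alone with the receptor kinase Tek at 0.64 ± 0.14, and antigen presentation genes too (median 0.58), 8 of 14 with RT1-DMa at 0.79 ± 0.11. Milk protein genes had a median of -0.39 (0 passed over the list alone), with Wap at -1.91 ± 0.79 and Lpo, lactoperoxidase, at -2.00 ± 0.68. Luminal epithelium genes were lower in 13 of 19 members (median -0.50, 1 fell over the list alone, adjusted p = 0.00129, and 0.778 with an estimated correlation). With an estimated correlation the adjusted p of the endothelial, antigen presentation and milk protein lists was 0.774, 0.774 and 0.822. Skeletal muscle genes had a median of -0.83 (adjusted p = 0.898 with an estimated correlation). In limma 0 of 18166 genes passed and 2350 had an unadjusted p under 0.05, 1232 higher and 1118 lower. With many genes changed at once, simulated log2 changes of 1 were called in 55.2% of cases here.

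**Figure D3:**
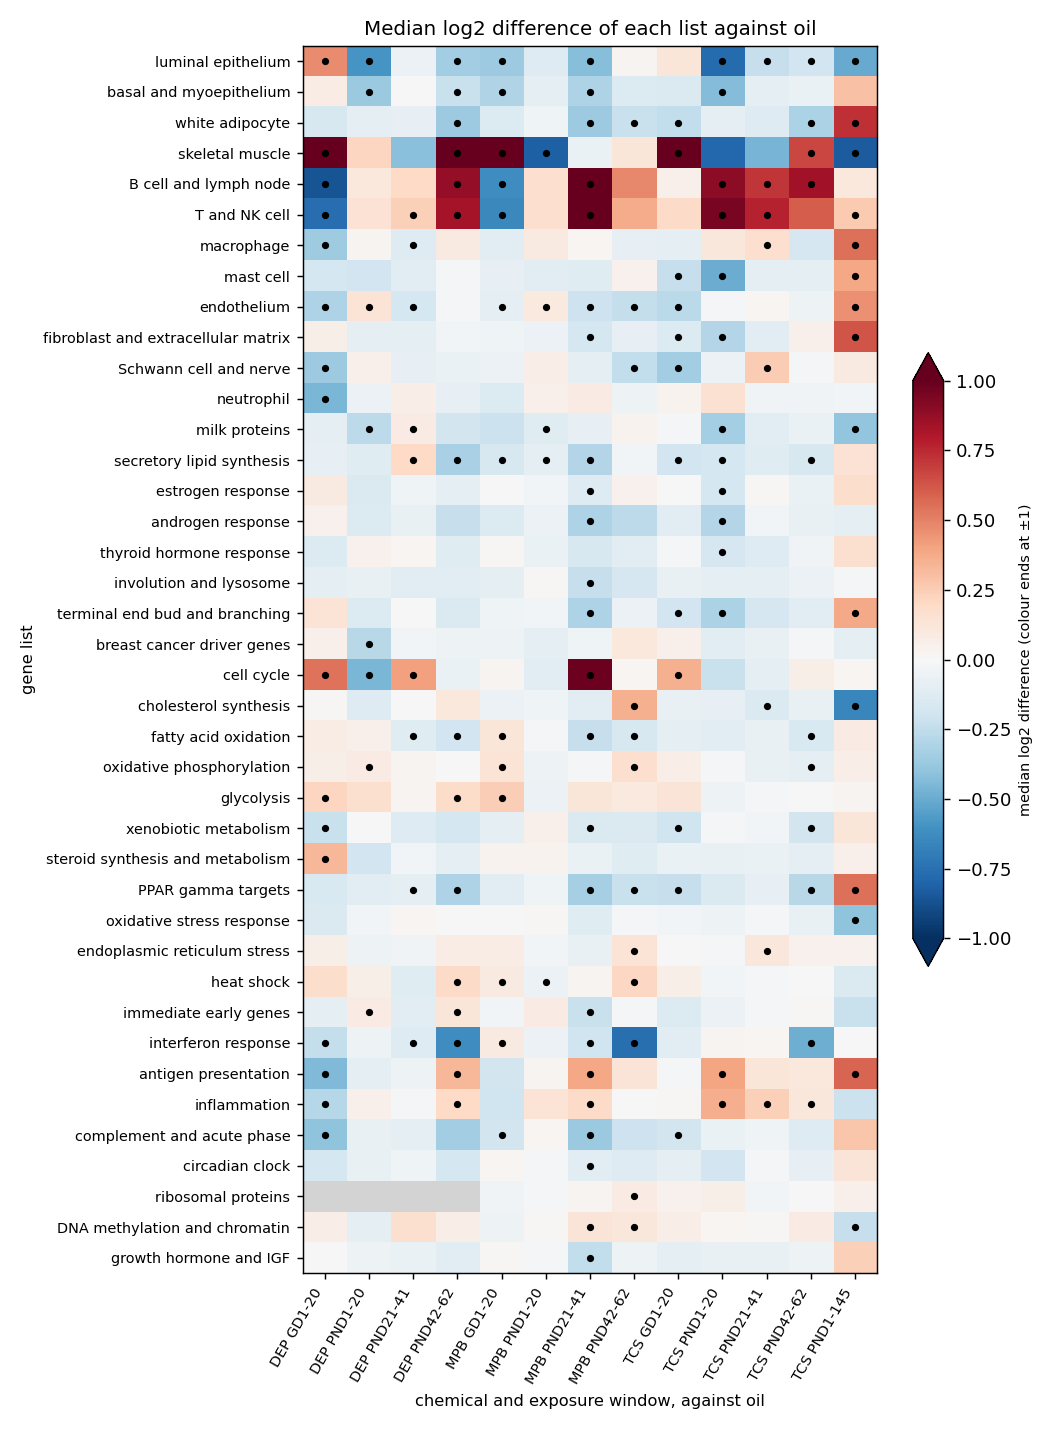
Heat map of the median log2 difference from OIL of 40 gene lists in the 13 comparisons of a chemical with OIL, with colours ending at ±1, dots for an adjusted p under 0.05 with the preset correlation, and grey where a list had too few members. Interferon response was lower than OIL for DEP, MPB and TCS after PND 42-62, by medians of -0.62, -0.76 and -0.49.

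Whether an effect depended on the window was tested on the differences themselves. The DEP effect on cell cycle genes was higher after GD 1-20 than after PND 1-20 in 24 of 24 members (median 1.00), 20 of them past the threshold over the list alone with Cdk1 at 1.33 ± 0.43, and the effect on endothelial genes was lower in 10 of 10 (median -0.43). Luminal epithelium effects were higher after GD 1-20 for DEP (median 1.06) and TCS (median 0.87). In DEP skeletal muscle (median 1.72, 16 of 16 positive, adjusted p = 0.0049) and B cell genes (median -0.98, 14 of 14 negative, adjusted p = 0.00343) moved in the same contrast. With an estimated correlation the adjusted p was 0.819 for both DEP lists named first and 0.969 for the others and for luminal epithelium in TCS. The OIL groups of both windows differed in the cell cycle, endothelial, luminal and muscle lists too, as given above, and these OIL arrays were part of the contrast. For MPB the effect on skeletal muscle genes was higher after GD 1-20 (median 3.16, adjusted p = 0.819 with an estimated correlation). By single genes 0 passed in limma for DEP, MPB or TCS, with 519, 484 and 880 at an unadjusted p under 0.05.

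Across the 4 short windows the effect on Nr1d1 differed for DEP (moderated F test, adjusted p = 0.00731) and the effect on Rtp4 differed for MPB (adjusted p = 1.98e-05), each the 1 gene to pass. The DEP effect on Nr1d1 was -1.44 after PND 21-41 and -1.26 after PND 42-62, and the MPB effect on Rtp4 was -1.28 after PND 42-62, with all 5 MPB arrays below all 5 OIL arrays. Rtp4 was 7.36 ± 0.20 in MPB after PND 21-41 and 7.35 ± 0.20 after PND 42-62 (SD, n = 5 each), while it was 7.65 ± 0.19 and 8.63 ± 0.36 in OIL, so it was the OIL level that differed between these windows. For TCS 0 genes passed, and 413 had an unadjusted p under 0.05 in limma. The DEP count was 0 within each batch, and the MPB count was 70 without MPB after PND 42-62 replicate 2 and 7 without MPB replicate 5 or OIL replicate 4 of that window.

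MPB and TCS were compared directly within each short window, at doses that the labels do not give as amounts. After PND 21-41 cell cycle genes were higher in MPB in 24 of 24 members (median 1.03), and after PND 42-62 heat shock genes were higher in MPB in 11 of 11 (median 0.22, 3 over the list alone). Interferon response genes were lower in MPB than in TCS after PND 42-62 (median -0.37, 1 passed over the list alone, Oas1a at -0.48 ± 0.13), and skeletal muscle genes were lower (median -0.59, 14 passed). After PND 1-20 matrix genes were higher in MPB in 20 of 20 members (median 0.24), and after GD 1-20 endothelial genes were higher in 10 of 11 (median 0.18). With an estimated correlation the adjusted p of each of these lists was 0.697. Gene by gene, 0 passed in limma after GD 1-20, PND 1-20, PND 21-41 and PND 42-62, with 772, 565, 610 and 1963 at an unadjusted p under 0.05, and 8 passed after PND 42-62 without MPB replicate 2.

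Across 6762 genes DEP and TCS after PND 42-62 correlated at r = 0.757 and DEP and MPB after GD 1-20 at 0.728. In 100 simulations of unchanged groups sharing the OIL arrays r was 0.322 to 0.447 and 0.449 to 0.542. With split OIL arrays r averaged 0.465 (0.143 to 0.666) and 0.537 (0.402 to 0.703). Muscle genes were higher in both chemicals of each pair, so shared muscle content stays open as a cause. For MPB and TCS, across 18166 genes, r was 0.513, 0.595, 0.598 and 0.37 in the 4 short windows, 0.498, 0.47, 0.41 and 0.41 in the simulation, and 0.265, 0.108, 0.283 and 0.105 with the OIL arrays split. DEP and MPB after PND 1-20 (r = 0.457) turned to -0.178 and DEP and TCS after PND 21-41 (r = 0.288) to -0.117 with split OIL arrays. Only Hp passed for both MPB and TCS after GD 1-20, against the same OIL arrays, which by themselves can raise the overlap.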

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

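The tests of clock genes for Nr1d1 and of an OIL group that was high by itself (for interferon genes and for Hp), and the choice of genes and scores searched for single outlying arrays, were made after the results were seen, while the tests of batch, of muscle and B cell content and of adipocyte content for these patterns were written down before.

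Interferon response genes were lower than OIL at PND 63 in all 3 chemicals. With B cell and muscle scores in the fit the median for MPB was -0.89 (SD over members 0.326), and it was -0.749 in batch 1 and -0.77 in batch 2, which argues against lymph node or muscle content and against batch as the cause (of the 16 muscle and 14 B cell markers, 0 are in another list, and 3 and 14 exceeded the median gene in 46 arrays not rich in muscle). The OIL arrays stood high by themselves, with a mean score of 0.758 ± 0.346 (SD, n = 5) at PND 63 and -0.01 ± 0.292 (n = 5) at PND 42 (exact permutation p = 0.00794, 2-sided). Between these ages MPB differed by 0.084 (exact permutation p = 0.349), DEP by 0.337 in its own table (0.103, where OIL differed by 0.838) and TCS by 0.196 (0.7, n = 3 each), and 1 of the 50 other arrays of the MPB, TCS and OIL set lay above the lowest OIL array at PND 63. An OIL group that was high by itself, a smaller rise with age in exposed animals and a mix of both stay open, because DEP and TCS rose in mean as well and the same OIL animals served all 3 chemicals.

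Nr1d1 was lower than OIL at PND 42, past the threshold for DEP. The difference was -1.609 ± 0.213 in batch 1 and -1.194 ± 0.206 in batch 2 (adjusted p = 0.786 and 0.685, fewer arrays). This argued against batch as the whole cause. With B cell and muscle scores in the fit it was -1.408 ± 0.158, from -1.443 ± 0.163, and the adjusted p went from 0.0283 to 0.0853 at a like size, the cause of which was not tested (0.000206 to 0.786 over the settings that leave out no single array). Of 11 other clock genes 6 shifted in DEP as their relation to Nr1d1 at other ages gives, where chance gives an SD of 1.66: Dbp (-0.43), Per3 (-0.42) and Cry1 (0.38) were among these 6, whereas Per1 (0.41) went against it. Against the same OIL animals Dbp, Per3, Cry1 and Tef (-0.39 in DEP) moved likewise in MPB (-0.282, -0.421, 0.351 and -0.291) and TCS (-0.547, -0.306, 0.441 and -0.309). Per1 was higher there too (0.436 and 0.741), while Bmal1, Per2, Bhlhe40 and Bhlhe41 differed in sign between the chemicals. Nr1d1 was also lower in MPB and TCS (limma, adjusted p = 0.135 and 0.653 over 18166 genes, not comparable with DEP over 6762). Clock phase at tissue collection and an effect of exposure cannot be told apart. The count lies within chance but weighs genes with hardly any shift like the others, and the labels give no hour of collection.

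Hp was lower than OIL after GD 1-20 for MPB and TCS, and for DEP in its own table by -0.44 ± 0.14 (adjusted p = 0.597). With the white adipocyte score in the fit the TCS difference was -0.604 ± 0.096 (adjusted p = 0.0311), against -0.602 ± 0.091 without it (0.00187 to 1 over the settings that leave out no single array). In batch 1 it was -0.582 ± 0.117 (adjusted p = 1) and in batch 2 -0.631 ± 0.147 (adjusted p = 0.302), so fat content and batch as whole causes were argued against. The OIL group after GD 1-20 was 0.564 above OIL after PND 1-20 (exact permutation p = 0.0159, 2-sided, n = 5 each), while TCS, MPB and, in its own table, DEP after GD 1-20 differed from OIL after PND 1-20 by -0.038, 0.007 and 0.136, and 5 of 24 other arrays at PND 21 lay above its lowest array. These values go with an OIL group after GD 1-20 that was high by itself. A gestational effect was not seen against OIL after PND 1-20 but is not excluded.

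Single arrays lay far from the rest of their group in 23 of 154 tests (a gap divided by the range), where chance gives about 7.7. For skeletal muscle the high arrays were DEP after PND 1-20 replicate 5 (score 3.93, others -1.03 to -0.61, ratio 0.916), DEP after PND 21-41 replicate 3 (1.73, ratio 0.807), MPB after PND 21-41 replicate 4 (3.91, ratio 0.963), MPB after PND 42-62 replicate 2 (-0.18, others -0.83 to -0.71, ratio 0.818) and TCS after GD 1-20 replicate 5 (4.92, others -0.65 to -0.39, ratio 0.954). For B cell and lymph node genes they were DEP after PND 21-41 replicate 1 (high, 0.84, ratio 0.853), MPB after PND 1-20 replicate 1 (low, -1.54, ratio 0.806), OIL after PND 21-41 replicate 5 (high, -0.06, ratio 0.786) and TCS after GD 1-20 replicate 5 (low, -1.77, ratio 0.875). The same 4 arrays stood out for T and NK cell genes, at 0.77 (ratio 0.816), -1.76 (ratio 0.839), -0.49 (ratio 0.779) and -1.62 (ratio 0.854). Cell cycle genes were low in DEP after PND 1-20 replicate 5 (-0.98, others 0.06 to 0.21, ratio 0.871) and TCS after GD 1-20 replicate 5 (-0.87, others 0.14 to 0.42, ratio 0.786).

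White adipocyte genes were high in MPB after PND 21-41 replicate 5 (-0.06, ratio 0.745) and low in OIL after GD 1-20 replicate 1 (-0.02, others 0.47 to 0.61, ratio 0.766), and clock genes were high in OIL after PND 21-41 replicate 1 (0.13, others -0.18 to -0.10, ratio 0.765). Hp was low in DEP after PND 1-20 replicate 5 (6.99, others 7.40 to 7.53, ratio 0.757). Nr1d1 was high in DEP after PND 42-62 replicate 4 (9.90, others 8.84 to 9.10, ratio 0.753) and in MPB after PND 42-62 replicate 4 (10.25, others 9.75 to 9.83, ratio 0.83). Rtp4 was high in DEP after PND 1-20 replicate 3 (7.24, others 6.85 to 6.89, ratio 0.906) and TCS after GD 1-20 replicate 4 (7.41, others 6.83 to 6.99, ratio 0.717).

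The effect on 1 gene each differed between exposure windows for DEP, Nr1d1 (moderated F test in limma, adjusted p = 0.00731), and for MPB, Rtp4 (adjusted p = 1.98e-05), and on 0 genes for TCS (413 at an unadjusted p under 0.05). Splits did not exclude chance for either count (11 of 100 as large for DEP and 19 of 100 for MPB), and in limma the DEP count was 0 in each batch alone (708 and 499 at an unadjusted p under 0.05). The effects within the windows are given above. Rtp4 stood at 7.36 and 7.35 in MPB after PND 21-41 and PND 42-62 and at 7.65 and 8.63 in OIL, so an OIL group at PND 63 that was high by itself stays open for Rtp4 too and was not tested for it.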

How the results depend on the processing

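Leaving out the arrays rich in muscle transcripts was chosen after the results were seen, and the other alternatives were planned. The 4 calls of a gene in the comparisons with OIL (Nr1d1, Rtp4, and Hp in MPB and TCS) kept their direction under each alternative that gave a value, and all 4 stayed past the threshold with array weights and with a mean log2 value of at least 5. They were lost in batch 1 alone, in batch 2 alone, in 21 of 40 fits that left out 1 array, and for the 3 that could be tested without the arrays rich in muscle transcripts, where the differences stayed near their size (Nr1d1 -1.609 from -1.443, Hp -0.488 from -0.557 in MPB and -0.57 from -0.602 in TCS). Of 101 list calls, all were lost with an estimated correlation. With no batch term 86 of 93 kept their side of the threshold and with a mean of at least 5 all 93 did. Signal over background limits the faint genes: genes with a mean log2 value under 5 were tested and left out only in that alternative, and of named clusters with a mean under 6 the DEP and OIL table held 0.376%. No paired analysis was possible because no array number in the labels occurs in both groups of a comparison, and the labels name no pair. The cause was not tested for the changes below, except that each batch alone, leaving out arrays and fitting only the groups compared use fewer arrays, and all transcript clusters tests more of them. For a count of 0 the number of genes at an unadjusted p under 0.05 in limma follows in brackets.

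With array weights the count of genes past the threshold was 656 for DEP after PND 1-20, 1375 for DEP after PND 42-62, 86 for MPB after GD 1-20, 1073 for MPB after PND 21-41, 2673 for MPB after PND 42-62 and 138 for TCS after PND 1-20. It was 1 for the DEP and 3 for the TCS difference between the perinatal windows, 144 for DEP and 3995 for MPB across the windows, 2256 for MPB against TCS after GD 1-20, 678 for OIL at PND 63 against PND 42 and 8 for OIL after GD 1-20 against PND 1-20.

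In batch 1 alone the count was 0 for DEP after PND 21-41 (58), MPB after PND 42-62 (2606), TCS after GD 1-20 (509) and DEP across the windows (708). It was 4 for MPB after GD 1-20, 1 for MPB and for TCS after PND 21-41, 303 for MPB across the windows, 2771 for MPB against TCS after GD 1-20, 3 for OIL at PND 63 and 2 for OIL after GD 1-20. Lists whose test turned direction were oxidative phosphorylation in DEP after PND 1-20 (median -0.118), cell cycle (0.03) and macrophage (0.035) in DEP after PND 21-41 and lipid synthesis (0.018) in MPB after GD 1-20. In batch 2 alone the count was 0 for DEP after PND 21-41 (442), MPB after GD 1-20 (3033), MPB after PND 42-62 (631), TCS after GD 1-20 (2311), DEP (499) and MPB (930) across the windows, OIL at PND 63 (1807) and OIL after GD 1-20 (2379), and 1267 for OIL at PND 42, of which 1223 were shared with the 4072.

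With no batch term the count was 0 for MPB (362) and TCS (630) after GD 1-20 and for OIL after GD 1-20 (598), 2546 for OIL at PND 42 (all shared) and 12 for OIL at PND 63. In 1 fit over all arrays of a data set it was 1 for DEP after GD 1-20, 5 for DEP after PND 42-62, 0 for MPB after GD 1-20 (912), 3 for MPB after PND 21-41, 498 for MPB after PND 42-62, 1 for TCS after PND 42-62 and 0 for OIL after GD 1-20 (1219). With only the groups compared it was 0 for MPB (378) and TCS (1300) after GD 1-20, 38 for OIL at PND 63 and 0 for OIL after GD 1-20 (1456). In the table deposited for the chemical it was 0 for MPB (671) and TCS (1635) after GD 1-20. For MPB after GD 1-20 it was also 0 with quantile normalization again (803), with eBayes trend and robust (705) and with all transcript clusters (1627). Quantile normalization again gave 2 for MPB across the windows, and all transcript clusters gave 21 for OIL at PND 63 and 2 for OIL after GD 1-20.

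With muscle and B cell scores as covariates the count was 0 for DEP after PND 21-41 (215), 4 for DEP after PND 42-62, 2 for MPB and 2 for TCS after GD 1-20, 52 for MPB after PND 42-62, 2 for DEP and 11 for MPB across the windows, 1645 for OIL at PND 42 (1355 shared), 512 for OIL at PND 63 (140 shared) and 12 for OIL after GD 1-20. Without the arrays rich in muscle transcripts it was 0 for DEP after PND 21-41 (109), 703 for DEP after PND 42-62, 63 for MPB after GD 1-20, 0 for TCS after GD 1-20 (2374), 59 for the MPB difference between the perinatal windows, 2029 for OIL at PND 42 (1939 shared), 232 for OIL at PND 63 (101 shared) and 0 for OIL after GD 1-20 (1867). Medians of the followed lists that turned there were -0.004 for luminal epithelium in DEP after GD 1-20, -0.017 for oxidative phosphorylation in DEP after PND 1-20, -0.137 for cell cycle in DEP after PND 21-41 and -0.115 for skeletal muscle in DEP after PND 42-62. In MPB after GD 1-20 they were -0.077 for skeletal muscle, -0.047 for oxidative phosphorylation, 0.163 for luminal epithelium and 0.624 for B cell, and in MPB after PND 1-20 0.118 for skeletal muscle.

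With the OIL arrays split between 2 chemicals, the correlation of their effects averaged 0.537 for DEP and MPB and 0.265 for MPB and TCS after GD 1-20, -0.178 for DEP and MPB and 0.108 for MPB and TCS after PND 1-20. After PND 21-41 it was 0.148 for DEP and MPB, -0.117 for DEP and TCS and 0.283 for MPB and TCS, and after PND 42-62 it was 0.383, 0.465 and 0.105 in the same order.

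Leaving out 1 array gave ranges of 0 to 1 for DEP after PND 21-41 and after PND 42-62 (1 without OIL or DEP replicate 4 of that window), 0 to 0 for MPB after GD 1-20 and 0 to 8 for MPB after PND 21-41 (8 without OIL replicate 2). They were 1 to 859 for MPB after PND 42-62 (859 without MPB replicate 2), 0 to 1 for TCS after GD 1-20 and after PND 1-20 (1 without OIL after PND 1-20 replicate 4), and 0 to 1 for the DEP and TCS differences between the perinatal windows (1 without OIL after GD 1-20 replicate 1, DEP after GD 1-20 replicate 2 or TCS after GD 1-20 replicate 2). Ranges were 1 to 3 for DEP (3 without OIL after PND 21-41 replicate 2) and 1 to 70 for MPB across the windows (70 without MPB after PND 42-62 replicate 2), 0 to 8 for MPB against TCS after PND 42-62 (8 without that array), 8 to 411 for OIL at PND 63 (8 without OIL after PND 42-62 replicate 3, 411 without OIL after PND 21-41 replicate 1) and 0 to 1 for OIL after GD 1-20. Of the list values 859 were unchanged in call, 74 lost it and 5 turned: oxidative phosphorylation in DEP after PND 1-20 (-0.021 to 0.164, lowest without DEP replicate 5) and MPB after GD 1-20 (-0.01 to 0.23, without MPB replicate 1), skeletal muscle in TCS after GD 1-20 (-0.008 to 1.53, without TCS replicate 5), and T and NK cell (-0.099 to 1.261) and B cell (-0.244 to 1.18) in TCS after PND 21-41, both lowest without TCS replicate 3.

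The alternatives on batch, on the groups in the fit, on the deposited table and on arrays rich in muscle could not give a value in the chronic window, nor batch 2 alone for TCS after PND 1-20, PND 21-41 and PND 42-62, where it held fewer than 2 TCS arrays. The deposited table of the chemical gave none for DEP, OIL alone or MPB against TCS. Fitting only the groups compared gave none for DEP at PND 42 and PND 63 or across the windows, and 1 fit over all arrays none across the windows or for OIL at PND 42 and PND 63. Leaving out arrays rich in muscle gave none for MPB and TCS after PND 42-62, and a mean of at least 5 none for DEP after PND 42-62.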

Other observations

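The tests by splits with array weights and by splits that keep the batches were chosen after results were seen, and the other splits of the arrays were planned.

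Several gene groups missed the threshold in every comparison of a chemical with OIL in which they were tested. Brown adipocyte medians ran from -0.074 to 0.249 (lowest adjusted p = 0.0836), erythroid medians from -0.148 to 0.023 (0.228), skin medians from -0.107 to 0.062 in the 9 comparisons that could be tested (0.312), and plasma cell medians from -0.367 to 0.316 (0.0804). Progesterone and prolactin response genes ran from -0.152 to 0.186 (0.0617), mammary progenitor genes from -0.13 to 0.105 (0.192) and Wnt signalling genes from -0.129 to 0.144 (0.0523). A missed threshold does not show that they were alike.

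Skeletal muscle and B cell lists are given here for the comparisons with OIL where the report leaves 1 or both out. The medians of the skeletal muscle and the B cell list were 0.22 and 0.11 for DEP after PND 1-20, -0.42 and 0.20 for DEP after PND 21-41 and 0.12 and 0.48 for MPB after PND 42-62, none past the threshold. They were -0.47 and 0.71 for TCS after PND 21-41, where the B cell list passed (adjusted p = 0.00496, and 0.834 with an estimated correlation), and the B cell median was 0.84 for TCS after PND 42-62 (adjusted p = 0.000223, and 0.797 with an estimated correlation). The muscle median was -0.07 for MPB after PND 21-41 and -0.78 for TCS after PND 1-20, and the B cell median 0.17 for MPB after PND 1-20, 0.05 for TCS after GD 1-20 and 0.11 for chronic TCS, none past the threshold. Muscle scores above 0.5 were found in OIL arrays too, up to 2.46 in OIL after PND 1-20 replicate 5 and 2.17 in OIL after PND 21-41 replicate 1, and in the chronic set in TCS replicate 2 (0.79) and OIL replicates 2 (0.60) and 3 (1.78). Clca1, a secreted regulator of chloride channels, and Alox15, a lipoxygenase, changed with age in OIL by 6.01 ± 0.29 (adjusted p = 2.87e-10) and -2.58 ± 0.18 (adjusted p = 4.03e-08) between PND 21 and PND 42, and Alox15 by a further -1.39 ± 0.21 (adjusted p = 0.00666) at PND 63.

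Other cell type lists passed the threshold at the preset correlation without being named for their comparison above, with adjusted p of 0.774 to 0.86 at an estimated correlation. Medians were -0.37 for Schwann cell, -0.36 for macrophage, -0.76 for T and NK cell and -0.46 for neutrophil genes in DEP after GD 1-20. They were 0.14 for endothelium and -0.37 for basal epithelium in DEP after PND 1-20, -0.13 for macrophage in DEP after PND 21-41, and 0.83 for T and NK cell and -0.22 for basal epithelium in DEP after PND 42-62. For MPB they were -0.37 for luminal epithelium, -0.10 for endothelium and -0.65 for T and NK cell after GD 1-20, -0.31 for basal epithelium, -0.17 for matrix and -0.21 for endothelium after PND 21-41, and -0.24 for Schwann cell after PND 42-62. For TCS they were -0.14 for matrix, -0.35 for Schwann cell and -0.23 for mast cell after GD 1-20, 0.95 for T and NK cell, -0.50 for mast cell and -0.43 for basal epithelium after PND 1-20, and 0.26 for Schwann cell and 0.17 for macrophage after PND 21-41. Luminal epithelium was at -0.19 in TCS after PND 42-62, and in chronic TCS macrophage stood at 0.55, T and NK cell at 0.26 and mast cell at 0.39. The sign differed between the batches for basal epithelium in DEP after PND 1-20 (-0.67 and 0.08), macrophage in DEP after PND 21-41 (0.04 and -0.38), T and NK cell in DEP after PND 42-62 (1.58 and -0.36) and in MPB after GD 1-20 (-2.14 and 1.66), and endothelium in MPB after GD 1-20 (0.13 and -0.43) and PND 21-41 (-0.25 and 0.03).

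In the other contrasts, cell type lists that passed without being named above had adjusted p of 0.28 to 0.969 at an estimated correlation. In OIL they were endothelium (-0.37), matrix (0.32), basal epithelium (1.01), Schwann cell (-0.73) and T and NK cell (-1.87) at PND 42, and mast cell (-0.25) at PND 63. In the differences between perinatal effects they were Schwann cell (-0.35), macrophage (-0.41) and T and NK cell (-0.91) for DEP, endothelium (-0.19), B cell (-0.81) and T and NK cell (-0.80) for MPB, and endothelium (-0.27), skeletal muscle (2.06) and B cell (-0.77) for TCS. For MPB against TCS they were T and NK cell (-0.86), skeletal muscle (1.03), luminal epithelium (-0.51), matrix (0.13), B cell (-0.69), Schwann cell (0.26) and white adipocyte (0.11) after GD 1-20, and luminal epithelium (0.62), B cell (-0.69), T and NK cell (-0.78), basal epithelium (0.32), mast cell (0.38) and neutrophil (-0.17) after PND 1-20. After PND 21-41 they were Schwann cell (-0.29), basal epithelium (-0.21), endothelium (-0.16), white adipocyte (-0.22), luminal epithelium (-0.23) and B cell (0.63), and after PND 42-62 luminal epithelium (0.16), endothelium (-0.19), Schwann cell (-0.26) and matrix (-0.18).

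To ask whether arbitrary groups give as many genes, the arrays of each comparison were split in other ways, the real split counted among them. These splits mixed the batches, with batch as a term of the fit. For DEP after PND 21-41, 8 of 100 splits gave at least 1 gene past the threshold (highest other 623), for MPB after GD 1-20 6 (highest other 2693), and for MPB after PND 42-62 5 (highest other 556), so chance could not be excluded for these calls by such splits. For TCS after GD 1-20, where the gene was Hp, 3 of 100 splits gave at least 1 (highest other 470). This share concerns the count of any genes, not Hp itself. OIL after GD 1-20 against PND 1-20, with no chemical, gave 2 of 100. Here and below, chance is called excluded at a share under 0.05 in the planned splits. The shares were not adjusted for the number of split tests, so some of them can arise by chance. A real count of 0 is reached by any split and tests nothing: all 100 reached it for DEP after GD 1-20, after PND 1-20 and after PND 42-62 (highest other 102, 0 and 699), MPB after PND 1-20 and PND 21-41 (395 and 160) and TCS after PND 1-20 (1), and so did all 56 splits for TCS after PND 21-41 (1) and PND 42-62 (72). Splits that call up to 2693 genes where the real one calls 1 point to some structure of the arrays, and what it was remains untested.

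By genes at an unadjusted p under 0.05, chance was excluded for MPB after PND 42-62 (3240 genes, 4 of 100 splits as many, highest other 4008). It was not excluded for DEP after GD 1-20 (471, 30 splits, highest other 2022), PND 1-20 (184, 30, 2060), PND 21-41 (153, 68, 1912) or PND 42-62 (995, 7, 1678), for MPB after GD 1-20 (731, 74, 5692), PND 1-20 (302, 87, 2831) or PND 21-41 (1788, 17, 3453), or for TCS after GD 1-20 (1236, 26, 4723), PND 1-20 (1133, 5, 2030), PND 21-41 (364, 51 of 56, 2014) or PND 42-62 (547, 40 of 56, 2162). With array weights it was excluded for DEP after PND 42-62 (1375 genes, 3 splits as many, highest other 2386) and MPB after PND 21-41 (1073, 3, 2214) but not for DEP after PND 1-20 (656, 5, 2265), MPB after GD 1-20 (86, 18, 3123), MPB after PND 42-62 (2673, 11, 4024) or TCS after PND 1-20 (138, 5, 1372). In the chronic window the 10 splits are too few for a share under 0.05: all 10 gave at least 0 genes past the threshold (highest other 0), and 1 gave 2350 at an unadjusted p under 0.05, the real one (highest other 2006).

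Across the windows 11 of 100 splits reached 1 for DEP (highest other 160) and 19 reached 1 for MPB (662), so chance was not excluded. A count of 0 again tests nothing: all 100 splits reached it for TCS across the windows (highest other 2) and for the differences between the perinatal windows of DEP, MPB and TCS (0, 807 and 1). For MPB against TCS all 100 splits likewise reached 0 after GD 1-20 and PND 1-20 (highest other 4543 and 1), and all 56 after PND 21-41 and PND 42-62 (1158 and 3371). Chance was excluded for age in OIL, where 1 of 100 splits reached 4072 genes at PND 42 (highest other 551) and 3 of 100 reached 142 at PND 63 (highest other 206), and for OIL after GD 1-20 against PND 1-20, where 2 of 100 reached 1 (highest other 49).

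Splits that keep 3 arrays of batch 1 and 2 of batch 2 in each group were run for results with a gene past the threshold or with a share under 0.05 above. For TCS after GD 1-20, where the gene was Hp, 2 of the 60 splits gave at least 1 gene (highest other 7). This share was under 0.05 too, although the call is lost with no batch term. For MPB after GD 1-20 it was 4 of 60 (highest other 2693), and chance was not excluded. For DEP after PND 21-41 and MPB after PND 42-62 it was 2 of 60 each (highest other 1 and 6), a share under 0.05. The planned splits gave 8 and 5 of 100 and did not exclude chance. Splits chosen after results were seen, and run only on selected results, do not overrule them. By genes at an unadjusted p under 0.05 in MPB after PND 42-62, and with array weights in DEP after PND 42-62 and MPB after PND 21-41, the real split alone reached 3240, 1375 and 1073 (highest other 3224, 1328 and 960), 1 of 60 each. Across the windows 5 of 100 such splits reached 1 for DEP (highest other 1) and 16 for MPB (highest other 285), and chance was not excluded. In OIL, 1 of 100 reached 4072 at PND 42 (highest other 1824), 2 of 60 reached 142 at PND 63 (highest other 182) and 2 of 60 reached 1 after GD 1-20 against PND 1-20 (highest other 49), so chance was excluded.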
